A study of Mus musculus with 6 samples.

How the data were processed

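RNA from Bv2 cells was sequenced in 6 libraries, 3 from control cells and 3 from cells after OGD/R. Per the labels' protocols, 1 ug of RNA per sample entered library preparation, reads were paired and 150 nt long, and cells had 30 min in nitrogen, 2 h of deprivation at 1% oxygen and 24 h of reperfusion. The same protocol speaks of an infection 72 h earlier, without saying whether it applies to these samples, and does not say whether control cells had their medium changed. If only the OGD/R cells were infected, infection could not be told apart from OGD/R. Nothing says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

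The deposited values are FPKM, printed to 2 decimals, in 1 table with a column per sample. The authors' genome build was GRCm38, per the submitters' processing notes; the aligner, the counting tool, the annotation and the rule that picked the genes are not given in the sources used here. The table is sorted by fold change (Spearman correlation of order and ratio -0.9999). The log2 ratio of group means nearest to 0 was 1.03 among higher and -0.97 among lower genes, so only within-table comparisons were made and no enrichment against all genes was computed. In 21 genes all control values were listed at 0, and in 23 all OGD/R values. Gene IDs were matched to GENCODE M21, on GRCm38, which placed 1227 of 1228; 2 names that had been turned into dates were restored from their IDs. Whether counting used strand is not given in the sources used here, so antisense genes and overlapping genes are uncertain.

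Because FPKM steps depend on gene length, the library size was sought at which low values (under 15 units) became whole multiples of 1 unit, given exon lengths from GENCODE. A value was called whole within its rounding error plus 0.03 units. This gave 7666000, 8248000 and 7628000 units for the control libraries and 8032000, 8466000 and 8666000 for the OGD/R libraries, with 97.2% to 100% of the values whole, against 42.1% to 51.8% at the best size over 3% away from the one taken and below 1.4 times it, and 18.8% to 20.1% by chance. Whether a unit is a read pair is not known. On simulated tables of 1227 genes the library sizes were recovered within 0.026%. The table itself took 5.1% to 5.6% of the units in control libraries and 4.0% to 4.1% in OGD/R libraries.

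Genes with a mean FPKM of at least 1 over the 6 libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit with group as the only factor, eBayes with a trend, two-sided), with Benjamini-Hochberg adjustment over the 852 genes and a threshold of 0.05. In simulated tables of 841 genes, limma recovered 94.9% of genes changed 2-fold and 98.9% of those changed 4-fold, and called 1.1% of the unchanged ones. Most simulated genes were unchanged, and each varied independently of the others. The deposited genes were picked for a difference and their libraries vary along a shared axis, so these rates need not hold for them. Before the data were examined, 36 gene lists were fixed, and the 11 with at least 5 tested members were tested with camera at a preset correlation of 0.01, against the other genes of the table. None of the 4 lists it called was called with an estimated correlation. Other steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

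Named genes follow a rule fixed at the same time as the lists. It takes the genes of the title, and the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap and whose higher group mean was at least 5 FPKM. It leaves out symbols starting with Gm and a digit, or ending in Rik or -ps, and IDs with no symbol, which here includes clone names. In each list with at least 5 tested members it takes up to 4 past the threshold with the largest fold change, in a list with none past it the member with the smallest p, and for other cell types the most abundant member. Alternatives covered the pseudocount, the expression filter, 2 scalings, the eBayes settings, a replicate block, each library left out in turn, an estimated correlation and the fry test. After seeing the data, voom on the recovered units, a block for library side (described with the other observations) and, for the lists, a regression of each library on GC content and log exon length were added.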

Results

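Gene expression was measured by RNA sequencing in Bv2 cells, an immortalised mouse microglial line, in 3 control samples and 3 samples after oxygen and glucose deprivation followed by reperfusion (OGD/R). Deprivation is a culture model of ischemia in which cells are kept without glucose in a low-oxygen gas, here 1% oxygen for 2 h in medium free of glucose and serum, before 24 h in standard medium. Values are FPKM for 1228 genes, of which 605 had the higher mean in OGD/R and 623 the lower. The log2 ratio of group means nearest to 0 was 1.03 among higher and -0.97 among lower genes, so the table holds genes picked for about a 2-fold difference on these same samples, by a rule not given in the sources used here. The other genes are not analysed here. The steps between low FPKM values corresponded to 7628000 to 8248000 counted units per control library and 8032000 to 8666000 per OGD/R library. A median gene of the table had 42 to 53 units per library.

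The comparison of OGD/R with control asks which genes of the microglial line differ 24 h after deprivation, and in particular where Cytip stood, a gene named in the title of the series. Cytip, which encodes an adaptor that binds cytohesins in immune cells, rose from 1.10 ± 0.285 FPKM in control to 7.96 ± 0.774 in OGD/R (SD, n = 3), or 7.26-fold (limma, log2 fold change 2.10 ± 0.14 SE, adjusted p = 7.6e-05). The gene, ENSMUSG00000026832, lies on chromosome 2 of GRCm38 from 58129137 to 58195532 on the minus strand. Lrrfip2, the other gene of the title, is not analysed here. Of the tested genes on lists fixed beforehand, 21 of 22 of the integrated stress response and unfolded protein response fell and 1 rose. In turn 19 of 19 of mitosis, 5 of 5 of DNA replication and 5 of 5 of cholesterol synthesis rose. Camera called these 4 lists at its preset correlation and none with an estimated correlation (adjusted p = 0.19, 0.070, 0.19 and 0.19). Of 852 genes tested, 829 differed at an adjusted p under 0.05 in limma, 397 higher and 432 lower in OGD/R, and 459 of them by at least 2-fold on the log2(FPKM + 1) scale. That scale understates the change of low genes, and the 2-fold count was 768 with a pseudocount of 0.1, 790 with 0.01 and 796 with voom on the recovered units. Because the genes were picked on these samples, neither count is independent evidence of how many genes respond to OGD/R. The picking also bears on the p-values of single genes, adjusted over the table or over a list. In limma 829 genes had an unadjusted p under 0.05, and adjustment left the same 829. In 1165 genes, or 94.9% of the table, the 3 OGD/R values lay all above or all below the 3 control values, where chance gives 10% for genes that were not picked; here the picking itself favours such separation.

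**Figure D1:**
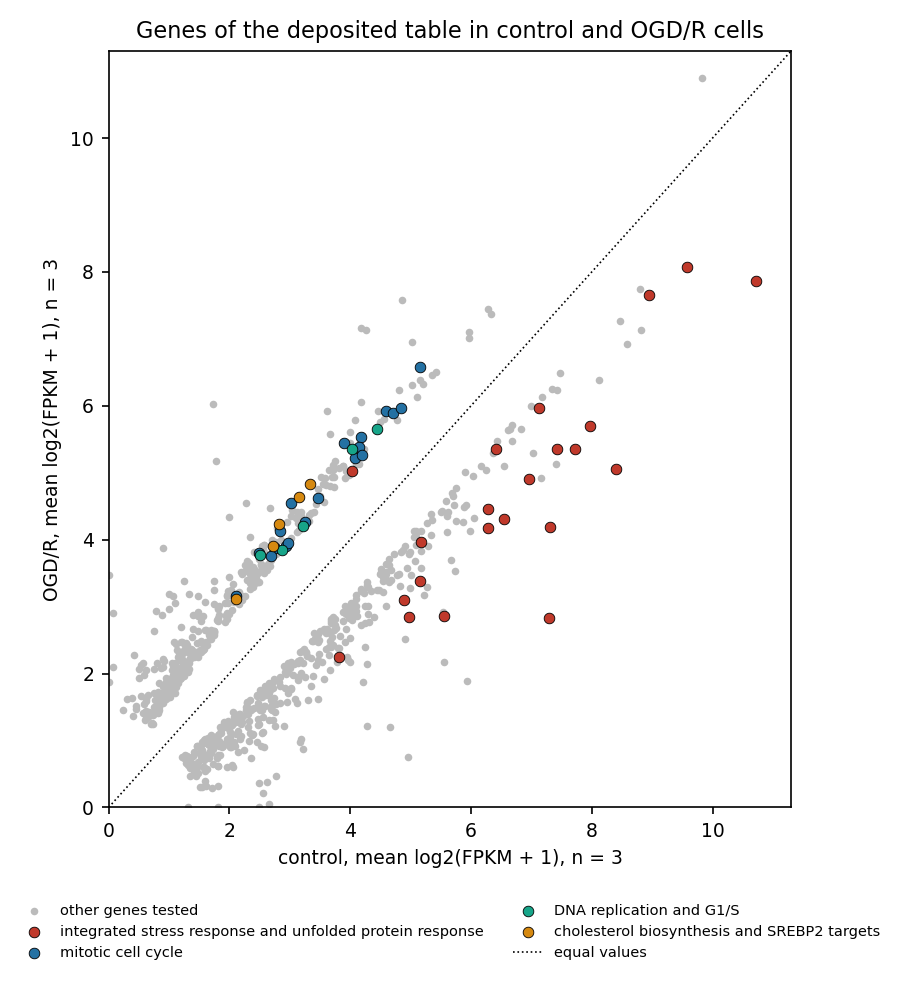
Mean log2(FPKM + 1) of the 852 genes tested in 3 control libraries (horizontal axis) and 3 OGD/R libraries (vertical axis), with the members of 4 gene lists coloured. The empty band along the dotted line of equal values shows that genes with small differences are not in the table; 21 of the 22 stress response genes lie below the line and all 19 mitotic genes above it.

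Many of the largest falls were in genes of the integrated stress response and the unfolded protein response, which cells switch on when proteins misfold in the endoplasmic reticulum or amino acids run short. Of the 42 genes on this list, 22 were tested, and 21 fell and 1 rose (22 adjusted over the list alone). Hspa5, which encodes the main chaperone of the endoplasmic reticulum (BiP), fell from 1695 ± 92.9 to 232 ± 15.8 FPKM (SD, n = 3; limma, log2 fold change -2.86 ± 0.11 SE, adjusted p = 2.4e-05). Herpud1, a component of the degradation machinery of the same compartment, fell from 338 ± 14.9 to 32.2 ± 1.38 FPKM (log2 fold change -3.35, adjusted p = 1.1e-05 in limma). Ddit3, the stress-induced transcription factor CHOP, fell from 163 ± 54.4 to 6.65 ± 3.69 FPKM, a log2 fold change of -4.46 ± 0.39, and Creld2 fell from 165 ± 58.1 to 17.4 ± 3.03 FPKM. Sdf2l1 and Ppp1r15a, whose product helps to restart translation after stress, fell with log2 fold changes of -2.38 and -2.70. Slc7a11, a cystine transporter named after its values were seen because it was the exception, rose from 15.3 ± 1.44 to 31.7 ± 3.06 FPKM. Syvn1, an endoplasmic reticulum ubiquitin ligase that is not on the list, fell from 45.4 ± 3.96 to 6.63 ± 1.03 FPKM. Against the other genes of the table the list was lower in OGD/R (camera, adjusted p = 1.6e-05), with adjusted p = 0.19 with an estimated correlation. As coordinates on GRCm38, Hspa5 lies on chromosome 2 at 34771970 to 34777547, Herpud1 on chromosome 8 at 94386438 to 94395377 and Ddit3 on chromosome 10 at 127290774 to 127296288.

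**Figure D2:**
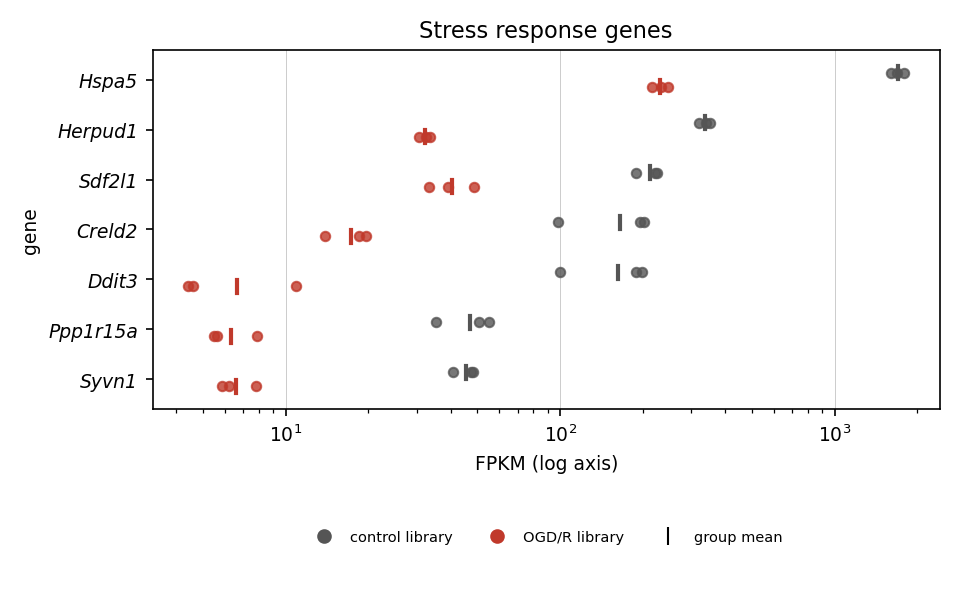
FPKM on a log axis of 7 stress response genes in each of the 3 control libraries (grey) and 3 OGD/R libraries (red), with a vertical tick at each group mean. For each gene every OGD/R library lies below every control library; Ddit3 has the widest spread, with group means of 163 and 6.65 FPKM.

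Of 33 listed genes of mitosis, 19 were tested and all 19 rose (19 adjusted over the list alone), with a median log2 fold change of 1.14. Higher protein-coding genes of the table were in general longer and lower in GC content (medians 4807 nt of exons and 45.9%) than lower ones (3370 nt and 53.5%), and the mitotic members had medians of 4919 nt and 46.1%. Mki67, a marker of proliferating cells, rose from 35.1 ± 8.69 to 95.3 ± 14.2 FPKM (SD, n = 3; limma adjusted p = 0.00060), and Hmmr rose from 13.9 ± 0.416 to 42.5 ± 2.08 FPKM. Bub1b, a kinase of the spindle checkpoint, and Cenpa, the histone of the centromere, rose with log2 fold changes of 1.35 ± 0.10 and 1.53 ± 0.23. The list was higher than the other genes of the table (camera, adjusted p = 1.6e-05; adjusted p = 0.070 with an estimated correlation). All 5 tested members of the DNA replication and G1/S list rose, out of 41 listed (5 adjusted over the list alone; camera adjusted p = 0.029; adjusted p = 0.19 with an estimated correlation). Among them were Rrm1 and Rrm2, the subunits of ribonucleotide reductase, at 15.4 ± 2.26 to 40.0 ± 3.31 and 20.8 ± 2.28 to 49.3 ± 5.38 FPKM, the cell-cycle repressor E2f8, with a log2 fold change of 1.27, and cyclin E1 (Ccne1), with 0.99. The 5 members had median exons of 5443 nt and a GC content of 48.7%.

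Genes of cholesterol synthesis and its regulation rose as well: 5 of 5 tested members of a list of 27 (5 adjusted over the list alone; camera adjusted p = 0.029; adjusted p = 0.19 with an estimated correlation). Insig1, which restrains the sterol-regulated transcription factors, rose from 9.13 ± 0.974 to 27.6 ± 0.204 FPKM (SD, n = 3; limma adjusted p = 7.9e-05). Idi1, an isomerase of the isoprenoid pathway, rose from 7.88 ± 0.160 to 24.0 ± 1.60 FPKM, Acat2 from 6.24 ± 1.94 to 18.0 ± 2.64 FPKM, and the sterol carrier Stard4 with a log2 fold change of 1.18. The 5 tested members had median exons of 3505 nt and a GC content of 48.2%. A sixth member of the list in the table was below the expression minimum and was not tested.

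**Figure D3:**
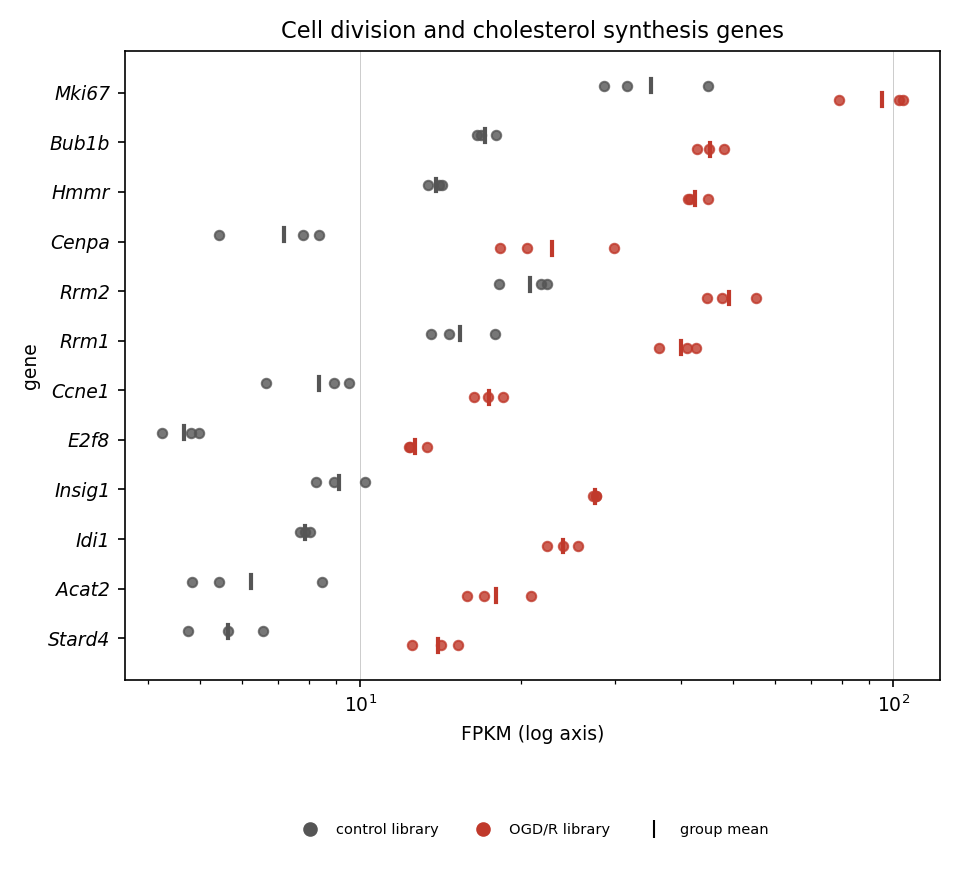
FPKM on a log axis of 12 genes of mitosis (Mki67 to Cenpa), DNA replication (Rrm2 to E2f8) and cholesterol synthesis (Insig1 to Stard4) in 3 control (grey) and 3 OGD/R (red) libraries, with a vertical tick at each group mean. Each gene is higher in every OGD/R library than in every control library.

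Genes tied to inflammation moved in both directions. Of 5 tested genes on a list of Cytip and partners of Cytip or Lrrfip2 known from earlier work, 4 rose and 1 fell (5 adjusted over the list alone), and the list did not pass the test against the other genes (camera adjusted p = 0.15). Beside Cytip, Itgb2, the beta chain of leukocyte integrins, rose from 22.8 ± 2.87 to 54.8 ± 0.365 FPKM (SD, n = 3; limma adjusted p = 0.00016), Nlrp3, the inflammasome sensor, from 7.92 ± 0.766 to 16.7 ± 0.340 FPKM, and Cyth1 from 4.12 ± 1.03 to 9.33 ± 2.13 FPKM. Cyth2, named after its values were seen as the member that fell, went from 15.2 ± 1.62 to 7.43 ± 1.66 FPKM. Among cytokines and inflammatory enzymes 1 of 6 tested genes rose and 5 fell (6 adjusted over the list alone; camera adjusted p = 0.15). Lcn2, an iron-siderophore binding protein, fell from 5.28 ± 2.52 to 0.163 ± 0.0874 FPKM, Ptgs2, which encodes cyclooxygenase-2, from 20.1 ± 2.10 to 6.16 ± 0.218 FPKM, and Csf1 and Tnfsf9 with log2 fold changes of -1.02 and -1.39. Among chemokines and their receptors 5 of 6 tested genes rose and 1 fell (6 adjusted over the list alone; camera adjusted p = 0.15). Ccl7 fell from 54.8 ± 19.1 to 10.8 ± 2.83 FPKM, while Ccl9 and the receptors Cxcr4 and Cx3cr1 rose with log2 fold changes of 1.29, 1.35 and 1.01. The ratios of their group means were 2.7, 4.42 and 4.74. Both receptors were low, at 0.783 to 3.46 and 0.373 to 1.77 FPKM, where the pseudocount shrinks the change.

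**Figure D4:**
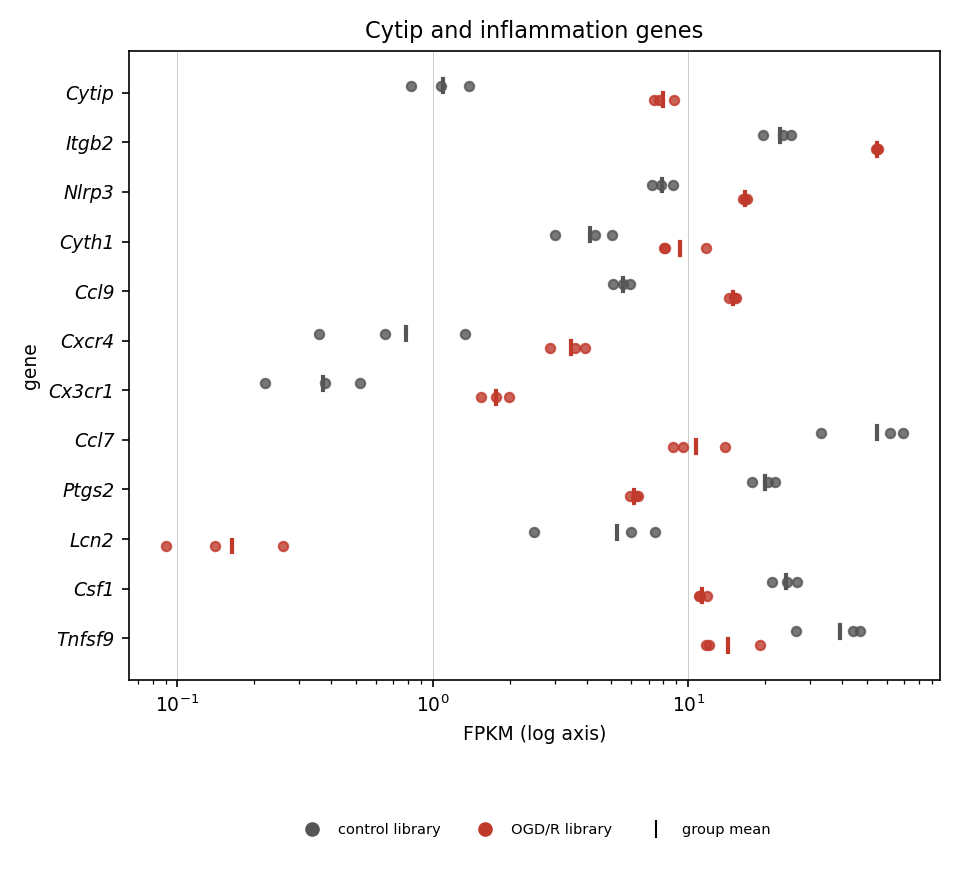
FPKM on a log axis of Cytip and 11 genes tied to inflammation in 3 control (grey) and 3 OGD/R (red) libraries, with a vertical tick at each group mean. Cytip, Itgb2, Nlrp3, Cyth1, Ccl9, Cxcr4 and Cx3cr1 are higher in each OGD/R library than in each control library, and Ccl7, Ptgs2, Lcn2, Csf1 and Tnfsf9 are lower.

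Toll-like receptors and their signalling partners moved both ways. Tlr8 and Tlr13 rose with log2 fold changes of 1.22 and 1.01, and the adaptors Ticam1 and Ticam2 fell with -1.10 and -1.25. Tlr8 was low, at 0.187 ± 0.127 to 1.82 ± 0.719 FPKM, a ratio of 9.75 that the pseudocount shrinks. The ratio of Tlr13, at 33.8 ± 3.85 to 69.1 ± 7.99 FPKM, was 2.05. Irak3, a kinase-family member of the pathway named after its values were seen, rose with 0.99, so 3 of 5 tested members rose and 2 fell (5 adjusted over the list alone; camera adjusted p = 0.77). The median of this list was 0.99 and its mean 0.18, and the fry test gave the opposite direction. Of 5 tested interferon-stimulated genes 2 rose and 3 fell (5 adjusted over the list alone; camera adjusted p = 0.76), with Ifit2 at 3.48 ± 0.247 to 7.26 ± 0.825 FPKM, and Isg15, Usp18 and Xaf1 lower, with log2 fold changes of -1.22, -0.94 and -0.76. Immediate early genes, which answer stimuli within minutes, gave 4 rises and 2 falls among 7 tested (6 adjusted over the list alone; camera adjusted p = 0.55). Nr4a1 rose from 0.713 ± 0.0586 to 6.72 ± 1.25 FPKM (SD, n = 3), Klf10 and Dusp5 rose with log2 fold changes of 1.86 and 1.41, and Klf4 fell with -1.48. Of 5 tested homeostatic microglial genes 4 rose and 1 fell (5 adjusted over the list alone; camera adjusted p = 0.15), including the receptors Cx3cr1 and P2ry6, the ectonucleotidase Entpd1, at 3.00 ± 0.165 to 9.88 ± 0.949 FPKM, and the transcription factor Mef2c, with 0.96.

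The remaining genes with the largest rises included Thbs1, encoding the matrix protein thrombospondin-1, which went from 0.0567 ± 0.0351 to 6.52 ± 0.761 FPKM (SD, n = 3; limma log2 fold change 2.83 ± 0.12 SE, adjusted p = 2.8e-05). Txnip and Arrdc4, related arrestin-domain genes that respond to glucose, rose from 28.4 ± 6.16 to 192 ± 27.2 and from 1.37 ± 0.0985 to 9.45 ± 0.549 FPKM. Cd83, a surface protein of activated antigen-presenting cells, rose from 3.86 ± 0.841 to 22.5 ± 3.94 FPKM, and Thbd, Pde7b and Chst10 rose with log2 fold changes of 1.98, 1.97 and 1.95. The mitochondrial tRNA genes mt-Tq, mt-Tw and mt-Ty rose with log2 fold changes of 4.30 ± 0.25, 3.39 ± 0.80 and 2.30 ± 0.53. Single libraries moved 2 of these values by over 1.5 times in fold. For mt-Tw the log2 fold change was 4.06 without control replicate 1 and 2.50 without control replicate 3, where it was listed at 0. For mt-Ty it was 2.94 without OGD/R replicate 3. These genes span 71, 67 and 67 nt, less than the 150 nt read length, and mt-Tw was no longer called with a pseudocount of 0.01 (limma adjusted p = 0.058, the highest of a range from 0.00296 over the settings tried). Control means of mt-Tq, mt-Tw and mt-Ty were 2.41 ± 1.09, 3.80 ± 3.90 and 11.5 ± 2.30 FPKM. At such lengths these are few counted units, so the size of each rise is uncertain, that of mt-Tq included. Among the largest falls, Gpr84, a receptor for medium-chain fatty acids, went from 45.9 ± 1.25 to 3.53 ± 0.601 FPKM and Avil from 5.38 ± 1.10 to 0.0333 ± 0.00577 FPKM. Sh2d6 and Acot2 fell with log2 fold changes of -3.07 and -2.40, and Bglap2 with -4.21 ± 0.59. Without control replicate 1 the value of Bglap2 was -4.90. Bglap2 has near-identical neighbours and Acot2 a close paralog, so both values are uncertain.

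Lists with fewer than 5 tested members were not tested as lists, and are given as numbers of tested genes. Genes that rose only were the mitochondrially encoded transcripts (3), and genes that fell only were NF-kB signalling (3), glycolysis (2), LXR targets (1), lysosome and autophagy (1), ribosomal proteins (1) and fibroblast and endothelial markers (1). Rises and falls were 3 and 1 for the inflammasome, 1 and 1 for hypoxia response, antigen presentation, and p53 targets and apoptosis, 2 and 2 for NRF2 and antioxidant genes, alternative activation, and cell adhesion and matrix, 1 and 2 for ferroptosis, 2 and 1 for disease-associated microglia, and 1 and 3 for phagocytosis and complement. Each of these counts was the same adjusted over the list alone; those for glycolysis and ribosomal proteins include Aldoa and Rpl13a entries at near-duplicate loci, which are uncertain. No listed gene was in the table for heat shock chaperones, nuclear-encoded oxidative phosphorylation, astrocytes, or lymphocytes and granulocytes, and the single listed gene in the table for each of the histone, neuron and oligodendrocyte lists was below the expression minimum. Off the histone list, the table held 3 tested histone genes, 1 higher (Hist1h2bh) and 2 lower (Hist2h3c2 and Hist2h2aa2), named after their values were seen. Of the markers of other cell types, Vwf fell from 3.66 ± 0.645 to 1.44 ± 0.321 FPKM (SD, n = 3; limma adjusted p = 0.0012), and Tubb3 was at 0.787 ± 0.334 and 0.190 ± 0.185 FPKM and Cspg4 at 0.0867 ± 0.00577 and 0.020 ± 0.017 FPKM, neither tested. The 1st principal component, which set the groups apart, held 87.1% of the variance over the tested genes. Spearman correlations were 0.938 to 0.978 within groups and 0.571 to 0.658 between them, in a table picked for differences between the groups.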

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

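Voom on the recovered units, the library side block, the regression on GC content and length and the share of variance without each replicate were chosen after seeing the data. Of 62 named genes that were tested, 61 kept direction and side of the threshold in every setting run, and mt-Tw lost its call with a pseudocount of 0.01. The number of changed genes was 829, and 789 to 829 without any 1 replicate; it was 409 with a filter of at least 5 FPKM, where 423 genes were tested. The number changed at least 2-fold was 459, and 444 to 506 without any 1 replicate; it was 768 and 790 with pseudocounts of 0.1 and 0.01 and 796 with voom, since a pseudocount of 1 shrinks the fold of low genes. Of 11 gene lists 4 were called, also without any 1 replicate (4 to 4), 0 with an estimated correlation, where 1 had an unadjusted p under 0.05 in camera, and 9 with fry, which asks only whether a list moves 1 way. With GC content and length regressed out of each library it was 4. Fold changes regressed on both over the genes off each list left medians of 1.07 for mitosis (95% bootstrap interval over genes, 0.82 to 1.14), 1.08 for DNA replication (0.92 to 1.35) and 1.24 for cholesterol synthesis (0.86 to 1.53). With the estimated correlation the camera adjusted p was 0.0697 for mitosis and 0.190 for the stress response, DNA replication and cholesterol synthesis. The other settings gave at most 0.0347. The estimate was -0.0348 for mitosis, -0.1551 for DNA replication and -0.104 for cholesterol synthesis, all below the preset 0.01, and 0.165 for the stress response. A higher correlation among members therefore accounts for the lost call at most in the stress response. No other cause was tested. With fry the adjusted p was 0.00023 for Cytip partners, 0.00025 for cytokines, 0.0011 for chemokines, 0.00079 for immediate early genes and 0.00057 for homeostatic microglia. Fry does not compare a list with the other genes of the table, so the picking of the genes may lower these values. Toll-like receptors and adaptors reversed with fry (adjusted p = 0.17, range 0.17 to 0.90; the cause was not tested). The share of variance on the 1st component was 87.1%, 84.3% with a pseudocount of 0.1 (the cause was not tested), and 85.9% to 91.3% without any 1 replicate. The replicate numbers showed no steady pairing. Deviations of same-numbered libraries correlated at 0.428, -0.349 and 0.375, and those of other pairs at -0.628 to 0.479. The signs go with library side, so a shared culture or batch cannot be excluded. A replicate block called 835 genes, 464 by at least 2-fold, and the same number of lists, 4. Depth limits genes with few units: the median gene had 42 to 53 per library. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05; the real split gave 829 genes, 459 of them by at least 2-fold, and 4 lists, and the highest of the others gave 4, 4 and 3 (1 of 10 splits gave as large a result each time). As the genes were picked for the real split, other splits had to give fewer genes. Each still called 2 or 3 lists. But each divides the control and OGD/R libraries unevenly and so keeps part of the group difference. These calls are therefore not a rate of false calls.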

Other observations

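All the tests and groupings in this part were chosen after the values were seen. Among 16 gene families and gene types compared by direction with Fisher's exact test (two-sided, against the rest of the table), 2 passed Benjamini-Hochberg adjustment. Kinesin genes, which encode microtubule motors, were higher in OGD/R for 10 of 11 in the table (exact adjusted p = 0.044). Of the 11, 4 are on the mitotic list, and of the 7 others 6 were higher. The 7 were not checked for other roles in cell division, so they are not evidence apart from the mitotic rise. Antisense transcripts were lower for 66 of 93 (exact adjusted p = 0.00087), but without known strand their reads cannot be told apart from those of the overlapping genes. Genes are not independent replicates, and the table was picked on these samples. Bootstrap intervals and permutation tests, here and in the part on processing, resample genes rather than libraries. They do not measure the spread between samples.

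Stress response genes were lower in OGD/R, in 21 of 22 tested members. With a linear trend of GC content and exon length over the other genes regressed out, the median log2 fold change was -1.87 (95% bootstrap interval -2.34 to -1.46). The members had -2.07 before. Their medians were 50.5% GC and 2714 nt, near the 49.3% and 3180 nt of the other genes, so such a fit could move them little. A linear trend as fitted in this picked table thus does not account for the fall. A trend over genes outside the table was not tested. With library side, described below, as a block the median was -2.00 (interval -2.31 to -1.44). Within sides the groups thus still differed. Each side holds libraries of both groups and the genes were picked for the group difference, so the block could hardly have removed the fall. A recovery difference that coincides with group would not be removed by such a block. How much of the fall goes with library side stays open. Of the fall, 13.5% (interval 4.1% to 21.4%) was also seen between control replicate 1 and the other controls. The shortest 25% of other lower genes had 17.2% (3.6% to 29.6%). A candidate explanation is that cells in OGD/R received fresh medium 24 h earlier and controls may not have. Txnip, which responds to glucose, was higher by 2.73 on the log2 scale. But the design confounds medium with group, so an effect of fresh medium cannot be told apart from an effect of deprivation. The same holds for every other group difference here, among them the rises of mitotic, DNA replication and cholesterol synthesis genes.

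All 9 mitochondrially encoded genes of the table were higher in OGD/R, 6 of them tRNA genes. Of 16 other genes under 200 nt, 5 were higher and 11 lower, with a median log2 fold change of -1.55 against 2.11 for the tRNA genes (exact permutation test, two-sided, p = 0.0076), but most lay near the floor in a table without small changes, and the outcome depends on the limit of units: p was 0.034 for the 9 above 10 units in some library (3 higher, 6 lower) and 0.071, the smallest possible, for the 2 above 25, both lower. Better recovery of short RNA therefore stays open. Within groups 5 of the 9 varied with the library difference described below, being highest in control replicate 1 among controls and lowest in OGD/R replicate 3, which may add to the spread. Longer protein-coding genes were relatively higher in control replicate 1. These 5, all short, thus went against the length trend of that library difference. With library side as a block the median of the mitochondrial genes was 1.77 (95% bootstrap interval 1.09 to 2.89). Within sides the groups thus still differed. In 8 of the 9 genes the groups did not overlap, and each side holds libraries of both groups. In genes picked for the group difference the block could therefore hardly have removed the rise. A recovery difference that coincides with group would stay, and an effect of OGD/R remains a hypothesis.

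Libraries also differed within groups along 1 axis, which held 62.6% of the within-group variance and set control replicate 1 and OGD/R replicates 1 and 2 apart from the other libraries. Across 635 protein-coding genes the axis followed exon length (Spearman rho -0.448; -0.421 in higher and -0.368 in lower genes), which is consistent with a different recovery of short transcripts between libraries. Longer genes were relatively higher in control replicate 1 and OGD/R replicates 1 and 2. GC content tracked the axis less (rho 0.144), which argues against GC bias as the main source. With library side as a block 840 genes were called, 825 of them shared with the 829. No biological explanation was tested, since the axis crosses the groups.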
